A study of Homo sapiens with 6 samples.

How the data were processed

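Droplet-based single-cell RNA sequencing libraries were made with the 10x Genomics Chromium Single Cell 3' kit, version 3.1, per the labels' protocols. The labels' protocols also name a TRIzol extraction of total RNA, which is a step of bulk rather than droplet libraries; how it relates to these libraries is not given in the sources used here. Cell Ranger, Seurat, Scanpy and the build GRCh38 (hg38) are named in the submitters' processing notes, without roles; versions, the annotation release and the cell-calling settings are not given in the sources used here.

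The deposited files used were the barcode and feature lists of the filtered matrices of 3 libraries (CTR, UCSD and MP of MGH-U3). They hold identifiers and no numeric values. Each line of a barcode list was checked to be 16 bases with the suffix 1, and no barcode occurred more than once in a list. Each line of a feature list gives an Ensembl identifier, a gene symbol and a feature type. Count matrices, the Mets library and the RT4 libraries were not analysed here. The expression and cluster comparisons that had been laid down for the case that count matrices were present were therefore not made, and the filters on cells, doublets and genes planned for them were not applied. Depth per library, which would set the precision of expression values, is unknown.

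Groups were taken from the sample titles. Every phenotype of a cell line had 1 library, so no test between phenotypes was made and no p-value is given. Numbers of barcodes, shared barcodes and near-identical pairs carry 95% exact Poisson intervals, ratios of 2 counts carry exact conditional (Clopper-Pearson) intervals, and base shares carry 95% Wilson intervals. A count of 0 was taken to allow up to 3 counts. All these intervals and limits cover counting error only, and bases of 1 barcode are not independent of each other.

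Shared barcodes were exact matches of the 16 bases. The size of the pool behind an overlap was computed as the product of the list lengths divided by the number shared. Near-identical barcodes were pairs at Hamming distance 1, found within each list and, as a background, between lists. Barcodes were also described by their base composition, over all bases, by position and by their number of G bases, with slopes of the log2 frequency ratio from logistic regression. That description was added after the lists had been seen. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and the plot Matplotlib 3.10.9. On simulated lists of the real lengths, the interval of the pool size held the true size for 3 of 3 pairs of lists, and 10 of 10 planted pairs at distance 1 were found. The simulated pool was smaller than the pools computed from the real overlaps, and its sequences were random. The simulation therefore checks the calculation and does not mimic the real barcodes.

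Features were matched by identifier, without version, to the GENCODE 29 primary assembly annotation (GRCh38), which gave positions and gene types for 34616 of 36601. The other identifiers were not found in that release, so the authors counted against another annotation. The positions and spans given here are those of GENCODE 29 and may differ from theirs. Overlaps between genes are overlaps of whole gene spans on the same strand. A table of gene names held 36366 of the identifiers. Before the data were examined, 12 gene lists with 165 entries were fixed (luminal and basal urothelial, squamous differentiation, partial epithelial-mesenchymal transition and invasion, proliferation, hypoxia and glycolysis, interferon response, FGFR3 and RAS pathway, fibroblast, endothelial, immune and dissociation stress), with the rule that without count matrices genes are named only as present in or absent from the feature list. Alternatives tried were other definitions of a cell, of a shared barcode, of a near-identical pair and of a matched feature.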

Results

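Single-cell RNA sequencing was applied to tumours grown from MGH-U3 and RT4, established human cell lines of non-muscle-invasive bladder cancer. Of the 6 samples described, 4 came from MGH-U3 and 2 from RT4, with 1 sample for each phenotype and cell line. The MGH-U3 samples were labelled CTR, UCSD (urothelial carcinoma with squamous differentiation), MP (mixed phenotype) and Mets (metastasis), and the RT4 samples CTR and UCSD. The design text names urothelial carcinoma among the phenotypes and the sample labels use CTR; the label CTR is kept here. The comparison the design implies is of squamous, mixed and metastatic tumours with the CTR tumour of the same line.

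Processed files of 3 libraries were used, CTR, UCSD and MP of MGH-U3. They held the list of cell barcodes (the bead sequences that mark the droplets called as cells) and the list of genes against which reads were counted. Counts per gene and cell were not analysed here, and neither were the Mets library or both RT4 libraries. Expression levels, cell clusters and differences in expression between phenotypes are therefore not reported, and the read or UMI depth of the libraries is unknown.

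Known marker genes of urothelial and squamous cells were all on the list of genes that reads were counted against. The feature list held 36601 human genes and was the same file in the 3 libraries, so a gene missing from 1 phenotype's list cannot set the phenotypes apart. All 165 entries of 12 gene lists fixed before the data were examined were present. The luminal urothelial list was covered for 20 of 20 genes, among them UPK2 and UPK1B, which encode uroplakins of the urothelial surface, KRT20, a keratin of umbrella cells, and the transcription factors GATA3 and PPARG. The basal list was covered for 15 of 15 genes, including KRT5, KRT14 and TP63. The squamous list was covered for 30 of 30 genes, including the cornified envelope precursor IVL, the small proline-rich protein SPRR3, the desmosomal cadherin DSG3, and the keratins KRT6A, KRT6C and KRT13. The lists for partial epithelial-mesenchymal transition and invasion (19 genes), proliferation (12), hypoxia and glycolysis (12), interferon response (13), the FGFR3 and RAS pathway (11) and dissociation stress (10) were covered in full. So were the human markers of fibroblasts (8), endothelial cells (6) and immune cells (9), cell types that tumour tissue can also hold. If the tumours grew in a host of another species, the genes of host cells were not on this list. Presence in the list says that a gene could be counted, not that it was expressed.

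In GRCh38 with the GENCODE 29 annotation, 10 of the 30 squamous genes were on chromosome 1, 6 on chromosome 18, 5 on chromosome 12, 3 on chromosome 17, 2 each on chromosomes 19 and 20, and 1 each on chromosomes 8 and 14. IVL spanned positions 152908545 to 152911886 and SPRR3 positions 153001747 to 153003856 of chromosome 1. KRT6A (52487174 to 52493257) and KRT6C (52468516 to 52473785) lay close together on the minus strand of chromosome 12, and KRT5 lay nearby at 52514575 to 52520687. KRT14 (41582279 to 41586921) and KRT13 (41500981 to 41505705) were on the minus strand of chromosome 17, and DSG3 (31447795 to 31478702) was on chromosome 18. KRT6A and KRT6C are near-identical paralogs, so reads of these genes can be hard to assign to 1 of them.

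Reads of some listed genes can also fall in a neighbour on the same strand. Of the 165 entries, 14 overlapped another listed feature on their strand. There were 0 such genes among the 30 squamous genes and 3 among the 20 luminal genes, namely GATA3, ELF3 and KRT7, the last of which overlapped KRT86. The basal list had 1, CD44. The hypoxia and glycolysis list had 5 of 12: SLC2A1, PGK1, LDHA, PFKFB4 and EGLN3. HLA-B of the interferon list overlapped HLA-C and LINC02571. Features without a position could not be checked, so the counts of overlapped genes may be too low. Overlap of whole spans does not show that counted reads were ambiguous.

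Of the 36601 features, 34616 (94.6%) were found by identifier in GENCODE 29. They comprised 19351 protein-coding genes, 14598 long non-coding RNA genes, 645 immunoglobulin or T cell receptor gene segments and 22 genes of other types. All features were of the gene expression type, 13 were mitochondrial, and 0 bore an identifier of another species. The identifiers carried 36591 distinct symbols, because 10 symbols were borne by more than 1 identifier, none of them a listed gene.

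Among these 3 libraries, UCSD had the most called cells. Its library held 20889 cell barcodes (95% exact Poisson interval 20607 to 21174), the CTR library 12448 (12230 to 12669) and the MP library 10612 (10411 to 10816). The UCSD library thus held 1.68 times as many barcodes as the CTR library (1.64 to 1.72) and 1.97 times as many as the MP library (1.92 to 2.02). The MP library held 0.853 times as many as the CTR library (0.831 to 0.875). Each phenotype was 1 library, so the differences have no replicate check and no test was made. The intervals cover counting error only, and the number of called cells depends on how many cells were loaded and how cells were called.

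The libraries shared few barcodes. CTR and UCSD had 79 barcodes in common (95% exact Poisson interval 62.5 to 98.5), UCSD and MP 65 (50.2 to 82.8), and CTR and MP 38 (26.9 to 52.2). The pool size was estimated as if each list were an independent draw from 1 pool of bead barcodes, all equally likely. These overlaps would then place the pool at 3291472 (2640998 to 4157424), 3410370 (2675677 to 4418844) and 3476268 (2532656 to 4912345) barcodes. The 3 estimates differed by less than their counting error, which does not show that all barcodes were equally likely. Barcodes also seen in another library made up 0.924% of the CTR list, 0.680% of the UCSD list and 0.952% of the MP list, and 2 barcodes occurred in all 3 lists.

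Barcodes that differed from another of the same library at a single base were found in the CTR library alone, as 4 pairs among 77470128 possible pairs. That is 0.0516 per 1000000 pairs (95% exact Poisson interval 0.0141 to 0.132). The UCSD library had 0 among 218164716 pairs, which allows up to 0.0138 per 1000000 by the limit of 3 counts and 0.0169 by the exact Poisson interval used for CTR, which overlaps that of CTR. The MP library had 0 among 56301966 pairs, which allows up to 0.0533 and 0.0655 by the same 2 limits. The difference itself was judged by the ratio of the rates. By the exact conditional method, the lower 95% limit of the ratio of the CTR rate was 1.86 against UCSD and 0.480 against MP. The limit against UCSD lay above 1, and the difference from MP was not detectable at these counts. Between libraries 0 were found among 613798516 pairs, which allows up to 0.00489 and 0.00601 per 1000000, and the lower limit of the ratio of the CTR rate to this one was 5.23. The comparison rests on 4 pairs in 1 library and covers counting error only. CTR was the only library with such pairs, and the limits make no allowance for singling it out.

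The barcodes of the UCSD library held fewer G bases than those of the other libraries. G made up 23.1% of their bases (95% Wilson interval 22.9 to 23.2), against 24.6% in CTR (24.4 to 24.8) and 24.6% in MP (24.4 to 24.8). C was higher, at 26.4% (26.2 to 26.5) against 25.1% in both CTR (24.9 to 25.3) and MP (24.9 to 25.3). T was also higher, at 26.0% (25.8 to 26.1) against 25.3% in CTR (25.2 to 25.5) and 25.4% in MP (25.2 to 25.6). A was 24.6% in UCSD (24.4 to 24.7) and 24.9% in CTR (24.7 to 25.1) and MP (24.7 to 25.1). Purines (A and G) together made up 47.7% in UCSD (47.5 to 47.8), 49.5% in CTR (49.3 to 49.7) and 49.5% in MP (49.2 to 49.7). The G share was lower in UCSD than in both other libraries at 15 of the 16 positions, and beyond the intervals of both at 5. CTR and MP differed beyond their intervals at 0 positions, which does not show that their shares were equal. This comparison was chosen after the barcode lists had been seen.

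**Figure D1:**
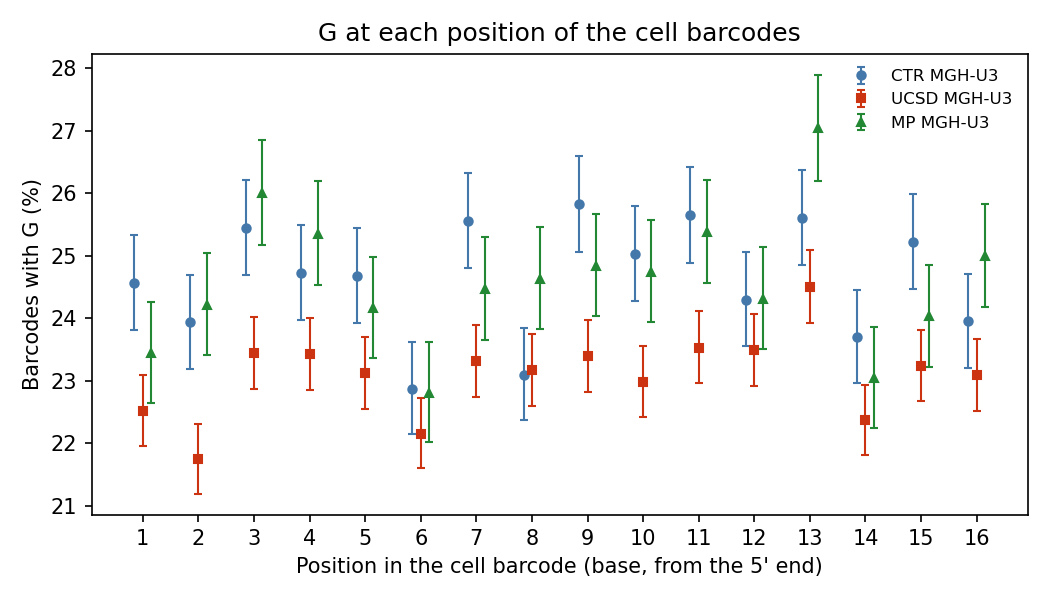
Percentage of cell barcodes with G at each of the 16 positions (x axis, from the 5' end) in the CTR, UCSD and MP libraries of MGH-U3. Points are 1 library each and bars are 95% Wilson intervals, which cover counting error only; the y axis does not start at 0. The UCSD points lie below both other libraries at 15 of the 16 positions.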

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

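The comparison of base composition, and its tests of read cycles and of the barcode pool, were chosen after the lists had been seen; the prediction for the graded loss was fixed before its result was computed.

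The UCSD library stood apart in the sequence of its cell barcodes, which are set by the beads and not by the tumour. C made up 26.4% of its barcode bases, above the 25.1% of the CTR library. T was higher as well (26.0% against 25.3%), and G was lower (23.1% against 24.6%). For a fault at a few read cycles, G shares were compared without the 3 positions of the largest drop. The difference in G share, UCSD minus the mean of CTR and MP, was -1.36 percentage points over the other 13 positions, with intervals apart. The lower share was thus not confined to those 3 positions. A first version of this test, which asked for a lower G share beyond the intervals at 3 or fewer or at 8 or more positions, gave 5 and decided nothing, and it was replaced by this one. The replacement draws on the same shares by position as the finding of a lower G share at 15 of the 16 positions. With that finding known, the replacement could hardly have come out otherwise, so it is not separate support against such a fault. A largely separate barcode pool is argued against. UCSD shared barcodes with the other libraries at 1.04 times the rate at which CTR and MP shared them (95% interval 0.723 to 1.53). This rate cannot exclude a pool that differs in part, or the same barcodes at other frequencies. A loss graded by the number of G in the barcode can be neither favoured nor excluded by its slopes. Other causes of a G share that is lower at nearly all positions can make both slopes negative as well. The log2 ratio of UCSD to CTR plus MP frequencies changed by -0.18 per G over 0 to 4 G bases (95% interval -0.21 to -0.15) and by -0.0705 per G over 4 to 8 (-0.11 to -0.03). The fall per G was steeper over 0 to 4, with intervals apart. The cause stays open: a candidate explanation is that more low-count droplets were called as cells in the library with the most barcodes, which was not tested because UMI counts were not analysed here, and a difference in library preparation or sequencing was not tested either.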

How the results depend on the processing

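The comparisons of base composition were added after the data had been seen; the other alternatives were fixed before the data were examined. The numbers of cell barcodes stayed within 1.5 times under each of their alternatives: leaving out barcodes found in another library gave 12333 for CTR, 20747 for UCSD and 10511 for MP, and counting barcodes at distance 1 as 1 cell gave 12444 for CTR and left the other libraries as they were. Matching at distance 1 or less added no shared barcode. Against the reverse complement of 1 list, each pair of libraries shared 0 barcodes, so that setting gives no chance level within the pool. At Hamming distance 2 instead of 1, near-identical pairs numbered 714 in CTR, 2037 in UCSD and 505 in MP. That is 9.22, 9.34 and 8.97 per 1000000 pairs. All lay above the 8.84 between libraries (8.60 to 9.07), and the interval of each library overlapped that of the pairs between libraries. Such overlap does not show equal rates. The ratio of the rates, used at distance 1, was not computed at distance 2, so a small excess within a library stays open. No barcode had a run of 5 or more equal bases, so leaving such barcodes out removed nothing. Matching features by symbol gave 36591, and older symbols added no list member. The G share of UCSD was lower than that of CTR and MP in the first 8 and in the last 8 positions. No leave-one-out was possible with 1 library per phenotype. The alternatives for expression and clusters were not run, as count matrices were not analysed here.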

Other observations

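Every one of the 43949 barcodes of the CTR, UCSD and MP libraries held an even number of purines: 0 of 12448 in CTR, 0 of 20889 in UCSD and 0 of 10612 in MP were odd. Under that rule, barcodes at distance 1 can differ only by an exchange of A with G or of C with T, so the finding that all 4 pairs at distance 1 in CTR did so carries no information about their origin. None of the members of those pairs occurred in another library (0 of 4 pairs).

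UCSD barcodes without G were 1.59 times as frequent as in CTR and MP together (256 against 178 barcodes, 95% exact interval 1.31 to 1.93), and barcodes with 7 or more G were 0.792 times as frequent (922 against 1285 barcodes, 0.727 to 0.863). The corresponding ratios of CTR to MP were 0.954 (0.703 to 1.30) and 1.08 (0.963 to 1.20).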
